A study of Mus musculus with 71 samples.

How the data were processed

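The series profiled Polycomb proteins and their histone mark in mouse J1 embryonic stem cells (ESC) and in cells differentiated from them. CBX7 is the chromodomain subunit of Polycomb repressive complex 1 (PRC1) that predominates in ESC, RING1B is the ubiquitin ligase of the same complex, and H3K27me3 is the histone methylation laid down by PRC2. Per the labels, the cells carried wild-type CBX7 (WT), a CBX7-CaPS form, a CBX7-mCaPS form or a CBX7 knockout, and were studied as ESC, as neural progenitor cells (NPC) at day 6 or 8, or as embryoid bodies (EB) at day 10. From the series title, the introduced part is a domain that Polycomb proteins of committed cells carry; what the letters of mCaPS stand for is not given in the sources used here. ESC were grown on feeder fibroblasts, per the labels. Knockout libraries were not analysed here.

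The authors deposited 9 peak tables with annotations, each giving the peak interval, the nearest gene and a value per library. The values are normalised signal, tags in the peak scaled to a total of 10000000 tags (10 M) per library, per the file headers, which also state each library's total. Peaks and annotations refer to the mm10 build, per the file headers. The submitters' processing notes name cutadapt 1.14, Bowtie2 2.3.4.3, SAMtools 1.9 and HOMER 4.10.4, and both the mm10 and dm6 builds. Drosophila chromatin was added to the ChIP samples as a spike-in, per the labels' protocols, and the column names carry a mark for normalised tag directories; whether the totals already contain a spike-in correction is not given in the sources used here. ChIP peaks were called against input and CUT&RUN peaks against an IgG control, per the series design text. The peak score column of the deposited tables is 0 throughout and was not used. The ESC tables for CBX7 and RING1B list the same 6326 intervals, so CBX7 was measured at those regions and not at peaks of its own. In the day-8 H3K27me3 table the headers call the columns pooled and give no number of libraries, while the labels list 1 such library per genotype. Those columns are treated as the authors' values. In the table of RING1B CUT&RUN in ESC the columns show the genotype but no sample number, and 2 further columns of per-sample values were not used.

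Multiplying each value by its library total gave whole read ends, 0.5 tag each, for 100% of values within a tolerance of at most 0.062 read ends. The header totals are thus those used in the scaling, and the counts behind the values can be recovered. Whether the totals equal the depth sequenced is not shown by this, and depth here means these totals. Header totals ran from 2.01 M tags for WT day-6 NPC of experiment 5 to 49.13 M for CaPS CBX7 of experiment 3. A count of 3 tags, the most that an observed 0 allows, corresponds to between 0.611 and 14.947 tags per 10 M. For some libraries the header total differs between tables, as for WT day-8 RING1B of experiment 3 with 10.34 M in the day-8 table and 11.81 M in the time course. Tables were therefore tested separately, and levels in different tables are not on a common scale. Confidence intervals at 95% and floors cover counting error only.

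Groups were CBX7 ChIP in ESC (3 WT, 3 CaPS), RING1B ChIP in ESC (3 and 3), H3K27me3 ChIP in ESC (2 and 2), RING1B ChIP in day-8 NPC (2 and 2), and a RING1B ChIP time course with 2 libraries for each genotype at ESC, day 6 and day 8. The experiment 3 libraries of the time course are the samples that also stand in the ESC and day-8 RING1B tables. Nothing in the labels says that libraries of a group came from separate cultures, so p-values rest on the spread between these samples, which may be technical. Values were tested as log2(value + 1) with limma 3.58.1 (empirical Bayes with trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all peaks of the table and a threshold of 0.05. On that scale the fold change of weak peaks is understated. The prior degrees of freedom that limma estimated were infinite in every comparison, so a peak's variance was the trend value at its mean signal. Its p-value therefore measures the spread usual among peaks of that strength, not the spread of its own libraries. It can be small where those libraries disagree. The number in a sample's title, which the series design text ties to experiments run together, entered as a block. Correlations of same-numbered libraries after removing group means lay between 0.04 and 0.3 for CBX7, between -0.02 and 0.23 for RING1B in ESC, at 0.09 for H3K27me3, at 0.25 for day-8 RING1B and between 0.06 and 0.22 in the time course, so the pairing rests on the design text. The plan had foreseen edgeR for counts and limma for normalised values, and the unit called for the latter. Tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

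A gene was measured if a peak annotated to it lay within 10 kb of its transcription start; of several, the strongest was used. There were 12 lists: Hox clusters (39 genes), Polycomb subunits (30), Wnt ligands and antagonists (25), cyclin-dependent kinase inhibitors (7), endoderm (20), fibroblast markers of the feeder cells (15), housekeeping (15), mesoderm (35), neural progenitor (48), pluripotency (20), primordial germ cell (10) and retinoic acid response (19). Lists were tested against all other genes with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's own genes move in a common direction. In addition, a list's median was ranked among 10000 random lists of the same size matched on mean signal. The percentile describes these libraries and is no p-value. Named genes are the 10 largest rises and falls past the threshold with the same sign in every pair; without a test, the 5 highest and 5 lowest ratios in the upper part of mean signal; the 2 strongest members of every list; and Hoxb1, Pax6, Sox1, Neurog2, Olig2, Gata4, Gata6, T, Cbx2, Cbx8, Cdkn2a and Cbx7. A few genes that the rule takes are not reported here.

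RING1B CUT&RUN in ESC (WT, CaPS, mCaPS), H3K27me3 CUT&RUN in ESC, RING1B CUT&RUN in EB and H3K27me3 ChIP in day-8 NPC have 1 column per genotype. These comparisons have no replicate check and no test. Ratios carry exact conditional binomial intervals from the tag counts, and peaks past 2-fold are counted. Counts given for counting error were simulated with a single ratio for all peaks, that of the tags summed over the peaks. Where that ratio lies near or past 2-fold, peaks cross the line in the simulation without counting error. Overlaps of peak sets used bedtools 2.31.1 with at least 1 bp and 100 shuffles of the intervals within chromosomes. The shuffles placed intervals anywhere on a chromosome. The CUT&RUN tables and the RING1B ChIP tables of ESC and of day-8 NPC hold only intervals within 10 kb of a transcription start. Shuffled shares thus understate the overlap that this limit alone would give. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

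Alternatives were a pseudocount of 5, scaling every library to the same sum over the peaks, the upper part of mean signal, peaks within 1 kb of a transcription start, leaving out the block, leaving out each library, a 1.5-fold count, gene assignment within 2 kb or by the mean of all peaks, unmatched random lists, and an overlap of at least 50% of the shorter peak. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered read ends, tags without the scaling to 10 M, camera with an estimated correlation (alone, within 2 kb or under the same-sum scaling), the matched percentile for tested comparisons, and leaving out chromosomes 6 and 8 or stretches of peaks at 0. Tags without the scaling to 10 M keep the depth of each library in the values, so their medians follow depth and give no direction of their own. The edgeR test called 2539 peaks lower and 2 higher in CaPS for CBX7 in ESC, 5 for RING1B in ESC and 0 for H3K27me3 in ESC and for RING1B in day-8 NPC. The pipeline was tested on simulated data with 200 changed peaks per comparison. With limma it recovered 40% of peaks lowered by 1 log2 unit and 86% of those lowered by 2 log2 units for CBX7 (6326 peaks), 8% and 50% for RING1B in ESC (6326 peaks), 16% and 54% for H3K27me3 in ESC (9195 peaks), 0% and 0% for RING1B in day-8 NPC (5393 peaks), and 4% and 36% for the WT change to day 8 (15091 peaks). For the difference between genotypes in that change it recovered 0% and 10% (15091 peaks). Rises of 2 log2 units were recovered more often than falls, at 100%, 76%, 92%, 2%, 76% and 20% in the same order, so counts of higher and lower calls do not compare evenly.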

Results

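The libraries covered CBX7, RING1B and H3K27me3 in mouse ESC and their derivatives, with the WT, CaPS or mCaPS form of CBX7. Among the ChIP libraries of CBX7 in ESC, those of WT held 13.13, 6.14 and 17.68 M tags in experiments 1, 2 and 3, and those of CaPS held 10.05, 2.63 and 49.13 M. The share of tags inside the 6326 peaks was 6.39%, 17% and 5.57% in WT and 2.63%, 7.1% and 3.63% in CaPS. For RING1B in ESC the shares were 6.57%, 19.3% and 9.46% in WT and 3.47%, 8.2% and 8.34% in CaPS, from totals of 7.09, 5.24 and 19.18 M tags and 5.33, 2.23 and 27.09 M tags. H3K27me3 ChIP in ESC, from experiments 1 and 5, had totals of 13.02 and 18.62 M tags in WT and 10.99 and 26.62 M in CaPS. Day-8 NPC libraries of RING1B, from experiments 4 and 3, held 5.23 and 10.34 M tags in WT and 9.52 and 25.34 M in CaPS. In the time course the libraries of experiment 5 were shallower, between 2.01 and 6.2 M tags, than those of experiment 3, between 11.3 and 25.34 M tags. CUT&RUN libraries of RING1B in ESC held 19.09 M tags for WT and 11.34 M for each of CaPS and mCaPS.

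All 6326 RING1B intervals of ESC lay within 10 kb of a transcription start, and 69.8% lay within 1 kb of a start on either side. The table thus holds only peaks near starts, and their closeness to starts is in part set by that limit. In the time course, which has no such limit, 61.1% of 15091 RING1B peaks lay within 10 kb and 36.9% within 1 kb. By annotation 31.6% of the ESC intervals were in promoters, 34.8% in introns and 21.5% in exons or untranslated regions. Of all 6326 intervals, 83.8% overlapped a RING1B CUT&RUN peak of ESC (1.69% for shuffled intervals), and 48.7% of the 10106 CUT&RUN peaks overlapped a ChIP peak (1.08% shuffled). H3K27me3 peaks overlapped 41.2% of them by ChIP (1.43% shuffled) and 54.7% by CUT&RUN (1.67% shuffled). The 2 kinds of H3K27me3 peaks shared 60.2% of the CUT&RUN set (2.75% shuffled). On differentiation, 45.8% of the ESC RING1B intervals overlapped one of the 5393 day-8 NPC peaks (0.88% shuffled), and 64.1% of day-8 peaks overlapped an ESC peak (1.02% shuffled). In day-8 NPC 61.4% of RING1B peaks overlapped H3K27me3 (1.47% shuffled). In day-10 EB 69.5% of 6547 RING1B peaks overlapped an ESC CUT&RUN peak (1.42% shuffled), and the reverse share was 42.9% (0.94% shuffled). Since shuffled intervals fell anywhere on a chromosome, the shuffled shares are too low a baseline for peak sets limited to the surroundings of starts.

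Whether CaPS changed how much CBX7 sits at Polycomb targets was asked by CBX7 ChIP in ESC (n = 3 per genotype, paired by experiment). CBX7 was lower in CaPS than in WT at genes of nearly every developmental group. At Hoxa6, in the HOXA cluster that patterns the body axis (6:52150360-52268794, peak centre in its promoter), it fell 2.55-fold, from 21660 ± 15700 to 7936 ± 4157 tags per 10 M (SD; log2 -1.35, SE 0.49, limma adjusted p = 0.0171). Pax6, a regulator of eye and forebrain development (2:105658441-105691679, promoter), fell 2.11-fold (1619 ± 923 against 3486 ± 2303 tags per 10 M, adjusted p = 0.00643). Gata4, a regulator of heart and endoderm (14:63238158-63257050, peak centre intergenic), fell 2.4-fold (adjusted p = 0.000459). The largest falls were at weak peaks, such as the promoter of Has3, a hyaluronan synthase (8:106870058-106870978), with 3.74 ± 3.62 against 26.1 ± 14.1 tags per 10 M (log2 -2.84, SE 0.46, adjusted p = 1.07e-07), and intron 1 of Grb14, an adaptor of insulin signalling (log2 -2.61, adjusted p = 1.07e-07). Rgs2, a regulator of G-protein signalling, had a log2 change of -2.59 (adjusted p = 2.09e-06) at its promoter. CBX7 rose at 4 peaks only by this test: near Prss41 (10.8 ± 7.35 against 0.82 ± 0.852 tags per 10 M, adjusted p = 0.00043), Jakmip1 (adjusted p = 0.028), Trim11 (adjusted p = 0.00918) and Pnldc1 (adjusted p = 0.0429). On read ends edgeR did not pass Jakmip1 (adjusted p = 0.0635) or Pnldc1 (0.0564). Without the pair of experiment 1 or of experiment 2, Hoxa6 (adjusted p = 0.429 and 0.629), Pax6 (0.315 and 0.406) and Gata4 (0.159 and 0.204) did not pass.

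By group, 37 of 38 measured neural progenitor genes fell (37 adjusted over the list alone), among them Sox1, a marker of neural commitment (log2 -1.18), Olig2, a regulator of oligodendrocyte and motor neuron fate (-1.18), and Neurog2 (-0.82). The same was seen for 22 of 24 Wnt genes (24 adjusted over the list alone), with Wnt5a at -1.32 and Wnt1 at -0.91, and for 26 of 30 mesoderm genes (26 adjusted over the list alone), with T, the brachyury gene of primitive streak, at -1.22. Camera placed these lists below other genes, with adjusted p = 0.00128 for neural progenitor, 0.00954 for Wnt and 0.0365 for mesoderm, and adjusted p = 0.789 with an estimated correlation for each. Without the block of experiments the values were 0.0531, 0.0867 and 0.186, and with genes assigned within 2 kb mesoderm had 0.174. Over all peaks 44.3% were called lower, and the counts given below for Polycomb, germ cell and housekeeping genes lay near that share. All 6 measured Hox genes fell (6 alone; camera adjusted p = 0.14), as did all 6 fibroblast markers (6 alone; 0.14), such as Pdgfra at -1.23. So did 10 of 12 endoderm genes (11 alone; 0.102), and all 5 inhibitors of cyclin-dependent kinases (5 alone; 0.532), with Cdkn2a, the INK4A/ARF locus, at -0.79. The Polycomb list had 6 of 13 (7 alone; 0.561), with Cbx8 at -1.12, and its median lay 0.06 below that of all genes on the log2 scale while camera pointed upward. Retinoic acid genes had 8 of 12 (9 alone; 0.509), and their median turned from 0.04 below all genes to 0.03 above under scaling to the same sum. Counts were lower for germ cell genes 3 of 7 (3 alone; 0.509), with Tfap2c at -1.25, and for housekeeping genes 1 of 2 (1 alone; 0.431), B2m at -1.18. Pluripotency genes had 2 of 8 (2 alone; 0.242): Prdm14 fell (log2 -1.39, adjusted p = 5.23e-06) as did Esrrb (-1.29), while Tbx3 (-0.69, adjusted p = 0.0707) did not pass; the list's median lay at percentile 99.99 of matched random lists.

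Over all 6326 peaks, limma called 2801 lower and 4 higher, the median log2 ratio was -0.85 (0.556-fold), and 60.9% of peaks were lower in each of the 3 pairs, with 82.8%, 85.3% and 75.4% lower in experiments 1, 2 and 3. The medians within experiments 1, 2 and 3 were -0.91, -1.14 and -0.44. Scaling every library to the same sum over the peaks moved the median to 0.11 and left 103 lower and 81 higher. Neural progenitor, Wnt and mesoderm then lay apart from all genes by -0.12, -0.18 and -0.1 on the log2 scale but passed no threshold (adjusted p = 0.181, 0.181 and 0.358), and Cdkn2a, Wnt1 and Neurog2 turned above 0. Tags without the scaling to 10 M gave 0 calls, the fit without the block of experiments gave 2, and leaving out the pair of experiment 1 or 2 gave 1177 or 1531.

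**Figure D1:**
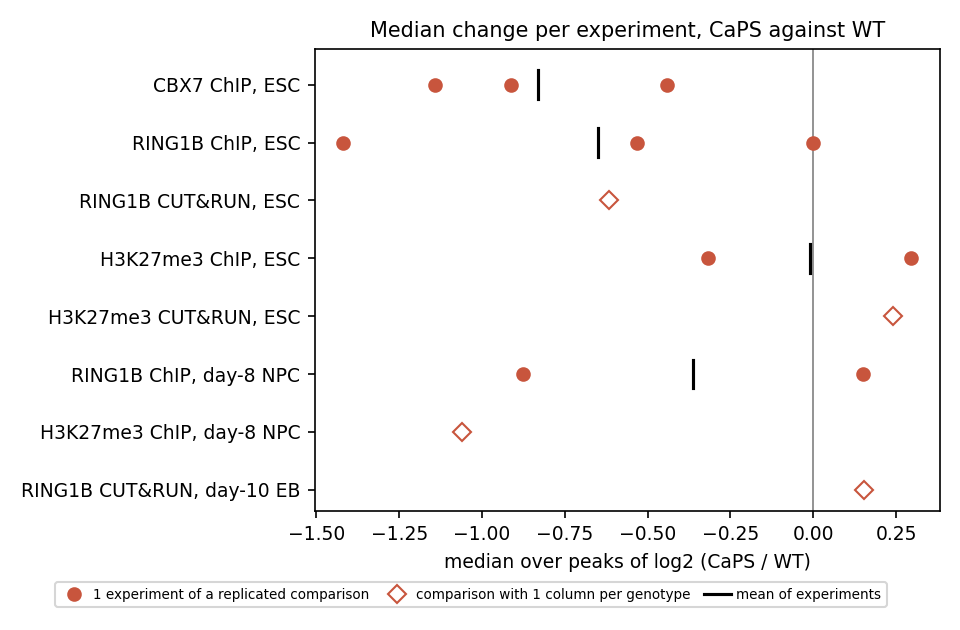
Median over peaks of the log2 ratio of CaPS to WT for each assay; filled circles are single experiments of a replicated comparison, open diamonds are comparisons with 1 column per genotype, and bars are means of experiments. CBX7 in ESC lies below 0 in each experiment (-1.14 to -0.44), while RING1B ChIP spans -1.42 to 0 in ESC.

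RING1B at the same 6326 regions asked whether the core of PRC1 followed (n = 3 per genotype, paired). RING1B was lower in CaPS at Cbln1, a synaptic organiser gene (8:87467009-87474032, intron 2; 561 ± 294 against 1680 ± 900 tags per 10 M, log2 -1.61, SE 0.38, adjusted p = 0.0242), and at Cdh8, a cadherin gene (8:99414130-99417773, promoter; log2 -1.86, adjusted p = 0.0239). It also fell at Pparg, the regulator of adipocyte fate (log2 -1.75, adjusted p = 0.049), Nkd1, an antagonist of Wnt signalling (-1.95, adjusted p = 0.0242), Ano10 (-2.89, adjusted p = 0.0242) and Slc24a3 (-2.91, adjusted p = 0.049). Without the pair of experiment 1, Cbln1, Cdh8, Pparg and Nkd1 had adjusted p = 0.943 each, and without that of experiment 2, Cbln1 (0.366), Cdh8 (0.0734) and Pparg (0.209) did not pass either. The strong targets had lower values in CaPS that did not pass: Hoxa6 at log2 -1.12 (adjusted p = 0.234), Pax6 at -0.9 (0.234), Gata4 at -1.09 (0.148) and Hoxb1 at -1.16 (0.118). No list had a member called among all peaks. Adjusted over the list alone, 11 of 24 Wnt genes, 10 of 38 neural progenitor and 8 of 30 mesoderm genes were lower. So were 3 of 12 endoderm, 3 of 6 fibroblast, 3 of 12 retinoic acid, 1 of 6 Hox and 1 of 8 pluripotency genes, and 0 of the Polycomb, cyclin-dependent kinase inhibitor, germ cell and housekeeping genes. No list passed camera (lowest adjusted p = 0.1, for Wnt). With genes assigned within 2 kb the Wnt list, at -0.31 relative to all genes, did pass (adjusted p = 0.0243, adjusted p = 0.816 with an estimated correlation). The Wnt median lay at percentile 3.99 and the pluripotency median at 99.97. The cyclin-dependent kinase inhibitor and retinoic acid lists had medians 0.03 and 0.01 above all genes while camera pointed downward.

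In all, limma called 9 peaks lower and 0 higher, against 1174 at an unadjusted p under 0.05; edgeR called 5 and DESeq2 873. The median log2 ratio was -0.67 (0.629-fold), with -0.53, -1.42 and 0 in experiments 1, 2 and 3, and 0.07 after scaling to the same sum, where 3 peaks were lower and 3 higher. Without the pair of experiment 1 the test called 0 peaks, without experiment 2 it called 17 and without experiment 3 it called 1099, and without the block 0. Of the 9 peaks, 6 lay on chromosome 8, which holds 6.15% of all peaks, and Pparg lies on chromosome 6; without those chromosomes 0 peaks were called. Peaks of chromosome 6 lay below those of the other autosomes in each of the ESC ChIP pairs, by medians of -0.35 to -0.13 for CBX7, -0.33 to -0.23 for RING1B and -0.38 to -0.25 for H3K27me3. Those of chromosome 8 did so too, by -0.2 to -0.09, -0.36 to -0.1 and -0.47 to -0.32, and those of chromosome 14, where Gata4 lies, by -0.13 to -0.11, -0.16 to -0.09 and -0.12 to -0.06. For RING1B in day-8 NPC chromosome 6 lay at 0.05 (0.01 and 0 in experiments 3 and 4), chromosome 8 at -0.13 (-0.17 and -0.1) and chromosome 14 at 0.07 (0.05 and 0.1). CBX7 calls without both chromosomes numbered 2396 lower and 4 higher.

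**Figure D2:**
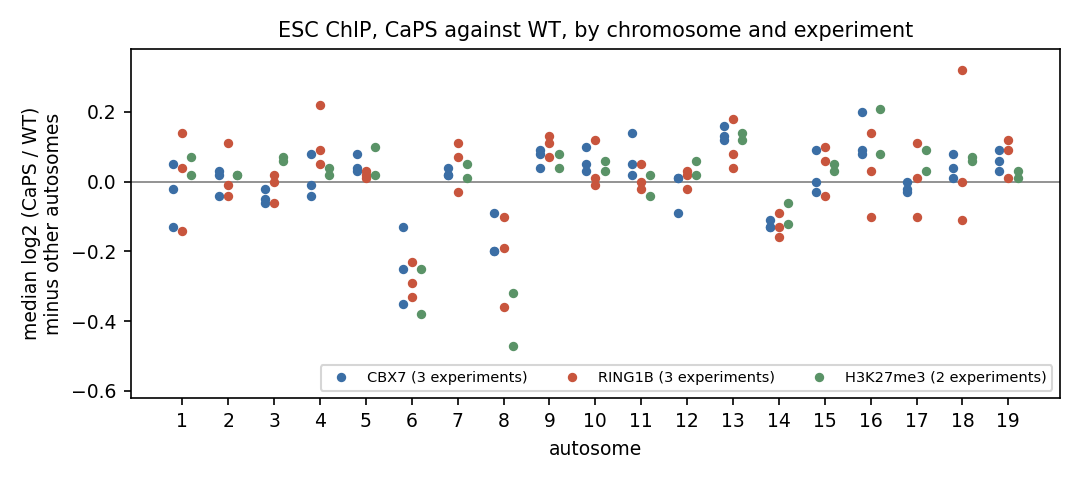
Median log2 ratio of CaPS to WT per chromosome relative to the other autosomes in ESC ChIP pairs, by antibody. Chromosome 8 lies below 0 in each pair, down to -0.47 for H3K27me3.

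RING1B CUT&RUN in ESC was a further assay of WT and CaPS, with 1 library per genotype and no replicate check for it or for mCaPS. RING1B was lower in CaPS at Gata4 (364.3 against 695.6 tags per 10 M, ratio 0.524, interval 0.468 to 0.585), at Wnt5a, a non-canonical Wnt ligand (ratio 0.524, interval 0.459 to 0.593), and at Tfap2c, a germ cell regulator (0.481, interval 0.396 to 0.575). The HOXA cluster peak annotated to Hoxa6 differed less (4918 against 6373 tags per 10 M, ratio 0.772), as did the HOXC peak annotated to Hoxc10 (0.875) and Cdkn2a (0.76). The lowest ratios were at Pantr1, Pantr2, Slc9a2, Il1rl2 and Fzd1, listed at 0 in CaPS against 729.7 tags per 10 M at Pantr1 in WT. The highest was at Osr1, at 0 in WT against 312.2 in CaPS. They lay in uninterrupted stretches of peaks at 0: 23 peaks of chromosome 1 (39361790-44552793) and 15 of chromosome 5 (3341502-9266723) in CaPS, and 2 of chromosome 12 (9029059-9585741) in WT, with floors of 2.65 and 1.57 tags per 10 M. Outside them the lowest were Kcnj6, Ednra (4.41 against 32.21 tags per 10 M), Cited4, Pcdh9 and Mtus1, and the highest Mllt10 (25.58 against 10.74), Zfp318, Irf2bpl and Mapk7. The median log2 ratio was -0.62 (interval -0.63 to -0.6), with 2278 peaks lower and 46 higher past 2-fold, where counting error around a single ratio would give 1718 and 29. Scaled to the same sum over peaks, the median was -0.04 and the counts 546 and 271. Relative to the median of all genes the Hox list lay higher by 0.33 (percentile 99.89 of matched lists; 7 of 8 above), and so did retinoic acid (97.25), mesoderm (96.92), cyclin-dependent kinase inhibitors (95.06) and neural progenitor (93.18). Percentiles of the others were 77.26 for Polycomb, 70.59 for germ cell, 67.23 for housekeeping, 44.78 for fibroblast, 38.32 for Wnt, 31.28 for pluripotency and 28.76 for endoderm.

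The mCaPS form was compared with both others by RING1B CUT&RUN. RING1B at Gata4 was 3.82-fold lower in mCaPS than in WT (181.2 against 695.6 tags per 10 M) and 2-fold lower than in CaPS (ratio 0.499, interval 0.42 to 0.591). At Pax6 the ratio to WT was 0.391 and to CaPS 0.622, at Olig2 0.325 and 0.484, and at Hoxa6 0.41 and 0.532. Cdkn2a had 165.8 tags per 10 M in mCaPS, a ratio of 0.477 to CaPS, whereas Kit (0.963) and the housekeeping gene B2m (1.11) differed by less than counting error. The lowest ratios to WT were at weak peaks, of Rab40b (2.65 against 25.67 tags per 10 M), Dock3, Rnf144b, Zfp30 and Ash2l. Relative to CaPS they were at Dock3, Sst, Zfp423, Arhgap31 and Trabd2b. Pantr1 (253.6 tags per 10 M) and Fzd1 (31.75) had tags in mCaPS, as did Osr1 (181.7). Against CaPS, mesoderm genes lay 0.49 lower than all genes on the log2 scale (percentile 0 of 10000 matched lists, 25 of 29 below), Hox genes 0.56 lower (0.31, 8 of 8 below) and neural progenitor genes 0.42 lower (0.11, 37 of 41 below). The other percentiles ran from 6.98 for pluripotency, 8.81 for cyclin-dependent kinase inhibitors, 9.98 for endoderm, 12.83 for Wnt and 13.82 for fibroblast to 38.94 for Polycomb, 52.83 for germ cell, 59.79 for retinoic acid and 69.24 for housekeeping. Against WT, neural progenitor genes lay 0.44 lower (1.74), Wnt genes 0.36 lower (6.74), mesoderm 0.39 lower (7.19) and endoderm 0.41 lower (9.92), and the remaining lists lay between 21.68 for germ cell and 85.15 for housekeeping. The median log2 ratio was -0.93 to WT, with 4536 peaks lower and 36 higher past 2-fold, and -0.33 to CaPS, with 1024 and 303. Simulated counting error around a single ratio gave 5876 and 6 to WT, and 1603 and 129 to CaPS. That ratio was already past 2-fold to WT (2.07% against 4.61% of tags in peaks). To CaPS it lay below the median over peaks (2.07% against 3.01%). Neither simulated count of lower peaks is therefore a baseline for counting error. Scaling to the same sum turned the medians to 0.12 and 0.16, with 315 lower and 607 higher than WT and 335 lower and 948 higher than CaPS, so the direction for all peaks depends on the scaling.

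H3K27me3, the mark that CBX7 binds, was measured in ESC by ChIP (n = 2 per genotype) and by CUT&RUN (1 column per genotype). By ChIP no gene passed the test: Hoxa9 stood at 3526 ± 823 against 4455 ± 2036 tags per 10 M (log2 -0.28, SE 0.54, limma adjusted p = 1), Pax3 at log2 -0.03, Gata4 at -0.26, Wnt5a at -0.35 and Cdkn2a at 0.12. Limma, edgeR and DESeq2 each called 0 of 9195 peaks, with 101 at an unadjusted p under 0.05 by limma, and the median of -0.03 joined pairs at 0.3 and -0.32. Scaling to the same sum gave 38 lower and 11 higher, and tags without the scaling to 10 M 6 and 9. No list passed camera (adjusted p from 0.487 to 0.754), nor did any member adjusted over the list alone. Pluripotency genes ranked at percentile 99.71 and cyclin-dependent kinase inhibitors at 98.92, and the other lists between 8.79 (Wnt) and 95.06 (retinoic acid). The Polycomb and germ cell lists had medians below 0 (-0.07 and -0.02) and means above it (0.05 and 0.08).

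By CUT&RUN H3K27me3 was higher in CaPS over cell-cycle inhibitor loci, at Cdkn2a (2174 against 1059 tags per 10 M, ratio 2.05, interval 1.93 to 2.18) and Cdkn2c (2.31, interval 2.11 to 2.53). Hox peaks, annotated to Hoxa3 (1.65) and Hoxb4 (1.74), were higher too, as was Nr2f1, an orphan receptor of neural patterning (1.91). The highest ratios were at Nr5a2, a nuclear receptor of early embryos (289.2 against 66.47 tags per 10 M, ratio 4.3), Nfib (3.37), Notum (3.3), Pura and Hipk2, and the lowest at Tmc7 (115 against 270.1), Ror1, Nmnat2, Cdh5 and Efcab2. Relative to all genes the 2 measured cyclin-dependent kinase inhibitors ranked at percentile 99.99, the Hox list at 99.46 (4 of 4 above), pluripotency at 98.6 and fibroblast markers at 3.84. The other lists ranked between 25.27 (Wnt) and 87.4 (neural progenitor). The median log2 ratio was 0.24 (interval 0.23 to 0.25), with 43 peaks lower and 207 higher past 2-fold, against 0 and 32 from counting error around a single ratio, and -0.08 with 155 lower and 81 higher after scaling to the same sum.

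In day-8 NPC, RING1B ChIP of CaPS and WT (n = 2 per genotype, paired) asked whether targets differ after differentiation. Lineage regulators differed in value without passing the test: Gata4 had 218 ± 55.6 tags per 10 M in CaPS against 993 ± 427 in WT (log2 -2.14, SE 0.8, limma adjusted p = 0.459), and Tbx3, a T-box gene of naive pluripotency and mesoderm, had a log2 ratio of -1.41 (adjusted p = 0.539). Sox2, the pluripotency and neural stem cell factor, stood at 2034 ± 625 against 752 ± 223 (log2 1.43, adjusted p = 0.499), Sox1 at 0.97 and Pax6 at 0.57. Limma, edgeR and DESeq2 called 0 of 5393 peaks, with 532 at an unadjusted p under 0.05 by limma. In simulations limma recovered 2% of peaks raised by 2 log2 units and 0% lowered by as much for this comparison (5393 peaks). With the scaling to 10 M this test could thus rarely detect differences of that size. Camera passed no list (adjusted p from 0.468 to 0.853). Adjusted over the list alone 2 of 13 Polycomb genes were lower and 1 of 3 housekeeping genes higher. The lowest Polycomb values were at Rybp, a peak of few tags (2.27 in CaPS against 11.76 tags per 10 M in WT), and at Cbx2. For Cbx2, CaPS and WT had 13.62 and 412.1 tags per 10 M in experiment 3, but 617.97 and 592.76 in experiment 4. Mesoderm genes ranked at percentile 0.16 and Wnt genes at 0.49 of matched lists, and the others between 5.06 (fibroblast) and 91.9 (housekeeping), with neural progenitor at 90.2. Camera pointed downward for Polycomb genes, whose median lay 0.28 above all genes, and the cyclin-dependent kinase inhibitors had a median of 0.07 and a mean of -0.07. The median over peaks was -0.37, with 0.15 in experiment 3 and -0.88 in experiment 4. Scaling to the same sum called 243 lower and 192 higher, the fit without the block 26 and 11, and tags without the scaling to 10 M 0 and 4 with a median of 0.66.

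H3K27me3 in day-8 NPC was compared through 1 column per genotype, which allows no test. The headers call these columns pooled, but the labels list 1 library per genotype. The Gata4 locus had 251.6 tags per 10 M in CaPS and 2368 in WT (9.38-fold lower, ratio interval 0.0969 to 0.116), and the peak at 1010001N08Rik, beside Gata6, a regulator of primitive endoderm (18:11046138-11060563), had 141.2 and 1828 (12.9-fold lower). Tbx3 was 5.54-fold lower (959.9 against 5317 tags per 10 M), Hoxb1 6.69-fold, and Jup, Lhfpl2, Dlc1 and Add3 were among the lowest. Pax6 and Sox1 went the other way, with ratios of 2.68 (693.6 against 258.5 tags per 10 M, interval 2.23 to 3.28) and 1.98, whereas Olig2 was 2.37-fold lower (1234 against 2923 tags per 10 M). The highest ratios were at Sall2 (4.55), Npas3 (4.04), Adgrv1, Rims2 and Plk3. Relative to all genes, mesoderm genes lay 0.43 lower (percentile 0 of 10000 matched lists, 25 of 30 below) and fibroblast markers 0.54 lower (3.96), and neural progenitor genes lay 0.18 higher (100; 19 below and 21 above) and endoderm 0.17 higher (95.61; 5 below and 8 above). With genes assigned within 2 kb, the neural progenitor list ranked at percentile 87.76. The others ranked between 14.16 (Polycomb) and 88.14 (germ cell), and no housekeeping gene was measured. The depths were far apart, 4.47 M tags in WT and 32.88 M in CaPS, with 16.4% and 8.2% of tags in peaks. The median log2 ratio was -1.06, with 4598 peaks lower and 242 higher past 2-fold. Simulated counting error around a single ratio gave 3953 and 75, but that ratio, 8.2% against 16.4% of tags in peaks, itself lay close to the 2-fold line. After scaling to the same sum the median became -0.09, with 1943 and 799. Without the scaling to 10 M it was 1.75 with 49 lower and 6253 higher, a shift that the difference in depth sets in advance. That value says nothing on the direction of the mark. Between the scaling to 10 M and the same-sum scaling the median moved from -1.06 to -0.09, so a change of the mark as a whole depends on the scaling.

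RING1B CUT&RUN in day-10 EB compared the genotypes in another differentiation (12.3 M tags each). Values at the main targets were close: the HOXC peak annotated to Hoxc10 had 3045 tags per 10 M in CaPS and 3178 in WT (ratio 0.958, interval 0.916 to 1), Pax6 a ratio of 1.03 and Gata4 of 1.02. Gata6 was lower (0.774, interval 0.649 to 0.919), and Sox2 (1.37, interval 1.19 to 1.6) and Cdkn2c (1.36, interval 1.2 to 1.53) were higher. The lowest ratios were at Wnk2 (5.69 against 20.32 tags per 10 M), Dnajb3, Ints3, Phb and Evx1os, and the highest at Rab11fip5 (20.32 against 4.88), Ralgds, Tcf3, Ppp1r12c and Lncenc1, a non-coding RNA of naive ESC (60.56 against 17.88, ratio 3.26). All lists lay inside the middle 95% of matched lists, from percentile 14.43 for cyclin-dependent kinase inhibitors to 90.56 for housekeeping. The median log2 ratio was 0.15, with 474 peaks lower and 858 higher past 2-fold, against 150 and 222 from counting error around a single ratio.

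The RING1B time course followed WT and CaPS cells from ESC to day 6 and day 8 of neural differentiation (n = 2 per genotype and stage, paired by experiment). In WT at day 8, RING1B fell at regulators of patterning. At Meis2, a homeobox cofactor (2:116059833-116077864, intron 2), it went from 2987 ± 634 to 168 ± 35.7 tags per 10 M (log2 -4.14, SE 0.4, adjusted p = 2.95e-21), and at Meis1 from 2913 ± 270 to 239 ± 40.2 (log2 -3.61, adjusted p = 5.17e-16). Pax6 fell from 4566 ± 778 to 852 ± 9.15 (log2 -2.41, SE 0.52, adjusted p = 5.22e-05), and log2 changes were -2.87 at T, -2.32 at Hoxb1, -1.62 at Olig2 and -3.57 at Zmiz1, a SUMO ligase gene. Among the rises were weak peaks of Fbxo43 (2.96), Theg (2.94) and Nme2 (2.75), and the promoter of Cbx7 itself (19.2 ± 1.34 to 45.9 ± 6.89 tags per 10 M, log2 1.21, adjusted p = 0.0156). At Fbxo43, Theg and Nme2 the call was lost without the experiment 5 library of ESC (adjusted p = 0.276, 0.11 and 0.396), at Fbxo43 and Theg without that of day 8 (0.11 and 0.193) and at Theg without the experiment 3 library of ESC (0.0612). The Cbx7 call was lost without the experiment 5 library of ESC (0.237) or the experiment 3 or 5 library of day 8 (0.204 and 0.0517). Sox2 (0.27, adjusted p = 0.732), Tbx3 (-0.37, 0.655) and Gata4 (-1.12, 0.058) did not pass. At day 6 the falls included Meis1 (log2 -2.58, adjusted p = 3.97e-08), Wnt1 (-2.01), Pax6 (-1.89, 0.00371), the anti-ageing gene Kl (-3.71, 4.63e-12) and Epha8 (-3.62), with Nme2 rising by 3.95. Without the experiment 5 library of day 6, Pax6 (adjusted p = 0.108), Kl (0.195) and Epha8 (0.0752) did not pass, nor did Pax6 without the experiment 3 library of ESC (0.0592).

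In WT, 22 of 24 Wnt genes fell by day 8 (22 adjusted over the list alone), with Wnt1 at -2.62 and Wnt5a at -2.27. Of retinoic acid genes 10 of 14 fell (10 alone), with Nr2f1 at -1.91. Of neural progenitor genes 22 of 40 fell (28 alone), of mesoderm genes 15 of 28 (19 alone) and of endoderm genes 7 of 13 (8 alone). Camera put these 5 lists below other genes (adjusted p = 7.15e-07, 0.00074, 0.00074, 0.0335 and 0.0439), and with an estimated correlation adjusted p = 0.488, 0.488, 0.698, 0.761 and 0.698. Mesoderm did not pass with genes assigned within 2 kb (0.0995) or under scaling to the same sum (0.256), nor endoderm under that scaling (0.198) or without the block (0.0598). The Wnt and retinoic acid medians stood at percentiles 0.02 and 0.13 of matched lists, the neural progenitor median at 94.75. Pluripotency genes lay above others (1 rose and 1 fell of 15; camera adjusted p = 0.00169, adjusted p = 0.488 with an estimated correlation). So did housekeeping genes (1 fell of 7, 3 higher adjusted over the list alone; 0.00343, adjusted p = 0.488 with an estimated correlation). Polycomb genes had 5 falls, with Cbx8 at -2.3, and 1 rise among 19 (5 and 1 alone; 0.494). Fibroblast markers had 5 of 8 lower (6 alone; 0.254), such as Pdgfra at -1.13, Hox 2 of 5 (2 alone; 0.133), germ cell 3 of 7 (3 alone; 0.468) and cyclin-dependent kinase inhibitors 1 of 5 (1 alone; 0.679). By day 6, 19 of 24 Wnt genes (21 alone; camera adjusted p = 5.24e-06), 8 of 14 retinoic acid genes (10 alone; 0.00245) and 15 of 40 neural progenitor genes (23 alone; 0.000397) had fallen, with adjusted p = 0.578, 0.578 and 0.792 with an estimated correlation. Pluripotency and housekeeping genes lay above others at day 6 too (2 of 15 and 2 of 7 rose; 0.00618 and 0.0221, adjusted p = 0.578 with an estimated correlation for each). The remaining lists did not pass at day 6. Falls numbered 4 of 28 for mesoderm (9 alone; 0.131), 5 of 13 for endoderm (6 alone; 0.164), 1 of 5 for Hox (1 alone; 0.254) and 1 of 8 for fibroblast genes (1 alone; 0.483). Polycomb genes had 4 falls and 1 rise among 19 (5 and 2 alone; 0.324), cyclin-dependent kinase inhibitors 1 fall of 5 (1 alone; 0.723) and germ cell genes 0 of 7 (0 alone; 0.57).

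Over all 15091 peaks limma called 3147 lower and 261 higher at day 8 in WT (edgeR 3488 and 172; median log2 -0.61) and 2209 lower and 243 higher at day 6 (edgeR 1869 and 104; median -0.47). Scaled to the same sum over peaks the medians became 0.36 and 0.25 and the calls 857 lower and 1351 higher and 605 lower and 1145 higher, with Pdgfra turning above 0; the lists kept their side of all genes. Tags without the scaling to 10 M gave 2 and 1 calls, and the fit without the block of experiments 1326 at day 6. Without the experiment 3 library of ESC, the experiment 3 library of day 8 or the experiment 5 library of day 8 there were 2187, 2118 or 2181 calls at day 8. Without the experiment 3 or 5 library of ESC or the experiment 5 library of day 6 there were 1285, 1554 or 644 at day 6.

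In CaPS cells RING1B at Sox2 rose on differentiation, from 1286 ± 359 in ESC to 4644 ± 2170 tags per 10 M at day 8 (3:34639212-34668491; log2 1.8, SE 0.47, adjusted p = 0.0018). It fell at Gata4 (2065 ± 126 to 289 ± 70.2, log2 -2.85, SE 0.45, adjusted p = 3.81e-08), Tbx3 (-2.25, adjusted p = 0.000146) and Meis2 (-3.36, adjusted p = 4.58e-14). Pax6 (-0.66, adjusted p = 0.432) and Sox1 (-0.58) did not pass. Among the largest rises were Igsf11 (3.71), Ap1s2 (3.66), Rbmxl2 (3.5), Tle4, a Groucho corepressor (3.3), and Syk (3.04). Sox2 did not pass without the experiment 3 library of ESC (adjusted p = 0.0787) or the experiment 5 library of day 8 (0.21), nor Tbx3 without the former (0.0616). Igsf11 did not pass without the experiment 5 library of ESC (0.09). At day 6 Sox2 rose by 1.65 (adjusted p = 0.0121) and Dirc2 by 3.43, and Tbx3 (-1.84, adjusted p = 0.00734), Meis2 (-2.71), Wnt1 (-1.86), Gata4 (-1.54), Ehd2 (-3.91) and Hist1h2ba (-3.39) fell. At day 6 the calls at Sox2, Tbx3 and Gata4 were lost without the experiment 3 library of ESC (adjusted p = 0.136, 0.186 and 0.253) or its experiment 5 library (0.169, 0.0583 and 0.0916). Wnt1 did not pass without the former (0.063), and Dirc2 (0.5), Ehd2 (0.0965) and Hist1h2ba (0.0739) not without the latter. Sox2 was also lost without the experiment 5 library of day 6 (0.269) and Gata4 without the experiment 3 library of day 6 (0.175).

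By day 8 in CaPS, 17 of 24 Wnt genes had fallen and 2 risen (19 and 2 adjusted over the list alone; camera adjusted p = 0.000102). The same held for 18 of 28 mesoderm genes (19 alone; 0.00144, and 0.0557 with genes assigned within 2 kb), 7 of 14 retinoic acid genes (9 alone; 0.000942) and 19 of 40 neural progenitor genes (23 alone; 0.00431). Each had adjusted p = 0.672 with an estimated correlation. Pluripotency (3 rose and 2 fell of 15, 3 and 2 alone; 0.00508, adjusted p = 0.672 with an estimated correlation) and housekeeping genes (1 rose of 7, 1 alone; 0.00431, adjusted p = 0.646 with an estimated correlation) lay above others. The remaining 6 lists did not pass camera. Germ cell genes had 5 falls and 1 rise among 7 (5 and 1 alone; 0.177) and Polycomb genes 4 falls and 2 rises among 19 (5 and 3 alone; 0.32). Falls numbered 2 of 5 for Hox (2 alone; 0.177), 4 of 13 for endoderm (5 alone; 0.443), 4 of 8 for fibroblast (4 alone; 0.444) and 1 of 5 for cyclin-dependent kinase inhibitor genes (1 alone; 0.32).

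At day 6 in CaPS camera passed Wnt (9 fell and 2 rose, 15 and 2 adjusted over the list alone; adjusted p = 0.000147), mesoderm (8 fell, 10 alone; 0.000654), retinoic acid (6 fell, 7 alone; 0.000434) and neural progenitor genes (2 fell, 2 alone; 0.0102), with adjusted p = 0.674, 0.674, 0.522 and 0.674 with an estimated correlation. With genes assigned within 2 kb mesoderm had 0.0743. Pluripotency (4 rose and 1 fell, 7 and 1 alone; 0.000654) and housekeeping genes (2 rose, 3 alone; 0.00134) lay above others, with adjusted p = 0.522 and 0.503 with an estimated correlation. The others did not pass. Falls numbered 1 each for Hox (2 alone; 0.202), endoderm (1 alone; 0.285) and fibroblast genes (1 alone; 0.285), and 0 for cyclin-dependent kinase inhibitors (0 alone; 0.376). Falls and rises numbered 1 and 1 for germ cell genes (1 and 1 alone; 0.285) and 2 and 3 for Polycomb genes (2 and 4 alone; 0.374). The Polycomb list had a median of -0.04 and a mean of 0.13. Limma called 2134 peaks lower and 246 higher at day 8 (edgeR 2574 and 179; median -0.48) and 763 lower and 369 higher at day 6 (edgeR 656 and 198; median -0.17). Scaling to the same sum gave 810 lower and 766 higher with a median of 0.13 at day 8, and 496 lower and 842 higher with a median of 0.16 at day 6. Tags without the scaling to 10 M gave 5 and 12 calls, and the fit without the block 1322 and 360. Leaving out the experiment 3 or 5 library of ESC gave 1457 or 1312 calls at day 8, and leaving out the experiment 3 or 5 library of day 8 gave 1215 or 935. At day 6 leaving out the experiment 5 library of ESC or of day 6 gave 204 or 683.

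**Figure D3:**
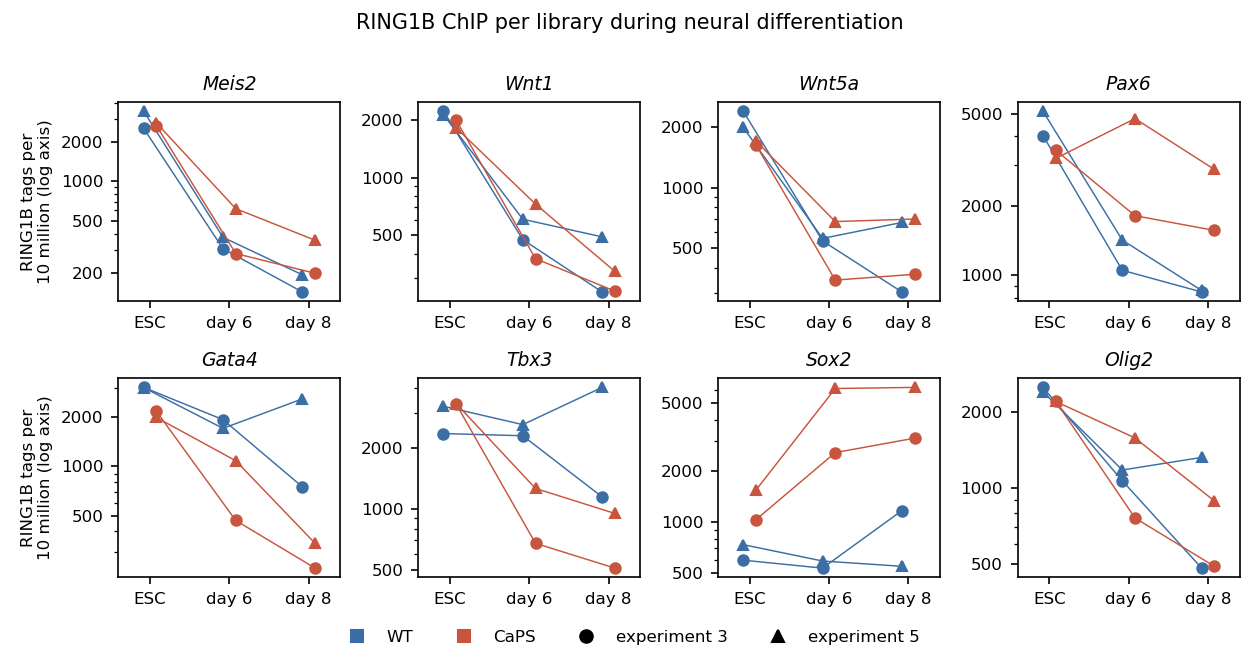
RING1B at named genes in each library of the time course, in tags per 10 M on a log axis, by stage; points are libraries of experiments 3 and 5. Sox2 in CaPS reaches 3109 and 6178 tags per 10 M at day 8, and in WT 1168 and 549.8.

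The difference between genotypes in the change from ESC was tested directly. By day 8 RING1B rose more, or fell less, in CaPS than in WT at Tox, an HMG-box gene (4:6987154-6991169, intron 1; difference in log2 change 2.77, SE 0.52, adjusted p = 0.000636), at Tle4 (19:14591593-14598164, intron 3; 2.78, SE 0.54, adjusted p = 0.00107), at Rragd, a GTPase of nutrient signalling (2.58, adjusted p = 0.00197), and at Ap1s2 (X:163909389-163911887, intron 1; 3.01, adjusted p = 0.00812), Tbc1d9 (2.92), Nova1, a neuronal splicing factor (2.49), and Nap1l4 (5.08, adjusted p = 0.0428, at a peak of few tags). It fell more in CaPS at 1010001N08Rik beside Gata6 (18:11045779-11061900, peak centre in intron 1 of Gata6; -2.43, SE 0.63, adjusted p = 0.0417). On read ends edgeR passed Tox (adjusted p = 0.000754), Rragd (0.00673), Tbc1d9 (0.00673), Tle4 (0.0214), Ap1s2 (0.0369) and 1010001N08Rik (0.0375), and not Nova1 (0.0899) or Nap1l4 (0.136). Each of these calls rested on libraries of experiment 5. Tox did not pass without that of WT day 8 (adjusted p = 0.567) or of CaPS day 8 (0.236), nor did Rragd without those (0.682 and 0.97) or that of CaPS ESC (0.388). Tle4 did not pass without that of CaPS ESC (1) or CaPS day 8 (0.97). Without any 1 of the 4 experiment 5 libraries, adjusted p lay between 0.117 and 0.985 for Tbc1d9, 0.325 and 1 for Ap1s2, 0.335 and 1 for Nova1 and 0.593 and 1 for Nap1l4. It lay between 0.417 and 1 for 1010001N08Rik, whose call was also lost without the experiment 3 library of CaPS ESC (0.186) or CaPS day 8 (0.383), as was that of Nap1l4 without the experiment 3 library of WT day 8 (0.103) or CaPS day 8 (0.156). Gata4 (-1.73, adjusted p = 0.397), Tbx3 (-1.89, 0.398), Sox2 (1.52, 0.517) and Pax6 (1.75, 0.509) did not pass, nor did Wnt1 (-0.1, 0.983). By day 6 the difference passed at Prkar2b, a subunit of protein kinase A (12:32059219-32060886, intron 1; 3.36, SE 0.64, adjusted p = 0.000586), Slc12a2 (3.82, adjusted p = 0.00218), Kl (3.22, adjusted p = 0.00218), Zfp428 (4.09), Mrap2 (3.93) and Sybu (3.92), of which edgeR passed Prkar2b (adjusted p = 0.0154) and none of the other 5. Without any 1 of the 4 experiment 5 libraries, adjusted p lay between 0.0567 and 0.532 for Prkar2b, 0.123 and 0.791 for Slc12a2, 0.171 and 0.847 for Zfp428, 0.17 and 0.847 for Mrap2 and 0.138 and 0.847 for Sybu. Kl did not pass without that of WT ESC (0.237), WT day 6 (0.871) or CaPS day 6 (0.765). The exon 5 peak of Cbx2, a CBX paralog of CBX7 (11:119027600-119028752), passed as well (3.19, adjusted p = 4.87e-06), with 440.9 ± 574 tags per 10 M in CaPS at day 6, and not without the experiment 5 library of CaPS day 6 (0.875) or WT ESC (0.0858). No list passed camera at either day (lowest adjusted p = 0.222 and 0.497). Mesoderm genes ranked at percentile 0.06 at day 8 and 0.02 at day 6, relative to all genes by -0.25 and -0.37, and after scaling to the same sum camera gave adjusted p = 0.00988 and 0.00152, with adjusted p = 0.94 and 0.91 with an estimated correlation. At day 8 mesoderm and germ cell lists had medians of 0.04 and means of -0.1 and -0.28. The housekeeping median lay 0.03 above all genes with camera downward. At day 6 the Hox, endoderm, retinoic acid and cyclin-dependent kinase inhibitor medians lay below all genes with camera upward.

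For day 8 limma called 30 peaks with a higher and 11 with a lower change in CaPS (edgeR 17 and 15, DESeq2 40 and 10), and for day 6 it called 53 and 3 (edgeR 5 and 0). The median difference was 0.2 at day 8 and 0.37 at day 6, and -0.18 and -0.06 after scaling to the same sum, where 50 higher and 66 lower, and 31 higher and 35 lower, were called. At day 8, leaving out the experiment 5 library of WT ESC gave 11 calls, of WT day 8 gave 3, of CaPS ESC gave 3 and of CaPS day 8 gave 1. Leaving out the experiment 3 library of CaPS ESC gave 91 and of CaPS day 8 gave 22. At day 6, leaving out the experiment 5 library of WT ESC gave 0, of WT day 6 gave 3, of CaPS ESC gave 6 and of CaPS day 6 gave 0. Leaving out the experiment 3 library of WT day 6, CaPS ESC or CaPS day 6 gave 604, 226 or 499. Without the block the calls were 1 and 2, and tags without the scaling to 10 M gave 0 at both days.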

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

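Tests of the same-sum scaling for the difference between genotypes, of peak strength for the neural progenitor genes and of the day-6 calls, and the edgeR fit, were chosen only after the results were seen. RING1B changed differently in CaPS and WT at 41 peaks from ESC to day 8 and at 56 peaks from ESC to day 6, by a test of the difference between the genotypes' changes over the 15091 peaks of the time course. At day 8 the peaks with a higher change in CaPS included Tox, Tle4 and Rragd, and those with a lower change the one in Gata6 annotated to 1010001N08Rik. At day 6 Prkar2b and Slc12a2 were among those with a higher change, and edgeR on read ends called 5 of the 56 peaks, without Slc12a2 (adjusted p = 0.583).

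Among the RING1B changes of the time course, a single factor per library was tested for the 41 peaks of day 8. Of them, 36 stayed called in the same direction under the same-sum scaling and 28 passed edgeR on read ends. The peaks had been selected at log2 values of 1.96 or more, which a scaling of whole libraries moves little. The edgeR fit used read ends of the same libraries. These counts thus exclude neither a yield factor nor low counts in the shallow libraries of experiment 5. For the 56 peaks of day 6 the median log2 value in the direction of the call went from 2.73 (quartiles 2.32 and 3.23) to 2.2 (1.81 and 2.86) under the same-sum scaling. These peaks had been selected at log2 values of 1.94 or more, and the scaling moves peaks by similar amounts. That their median stayed large was thus mostly set in advance. It does not exclude a factor per library that carried peaks past the threshold. Only 22 stayed called, since the values fell while their median SE stayed at 0.6, and the median adjusted p went from 0.0127 to 0.0599. Low counts stay open at day 6, where 5 passed edgeR although the median there was 2.17. The day-8 calls still rest on the libraries of experiment 5, since leaving out that of WT ESC, WT day 8, CaPS ESC or CaPS day 8 left 11, 3, 3 or 1, and a mistake in 1 library or a difference between the CaPS and WT cells both stay open at n = 2. In WT the falls by day 8 at Wnt and retinoic acid genes lay at percentiles 0.02 and 0.13 of lists matched on signal, which argues against peak strength as their whole cause, whereas the neural progenitor genes, at 94.75, lay inside the middle 95% of such lists. The Wnt genes lay at -1.61 relative to all genes in experiment 3 alone and at -1.11 in experiment 5, against the shallow libraries as the source. A fall of RING1B at Wnt and retinoic acid genes in differentiating WT cells therefore remains a hypothesis that these tests leave standing. Neither list passed camera with an estimated correlation, and cell composition was not tested.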

How the results depend on the processing

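Of 334 recomputed counts, medians and overlaps, 167 stayed within their limits, which are a factor of 1.5 for counts and the spread or counting interval for medians and shares, and 167 moved. Of 1052 recomputed values of gene lists 942 stayed, 14 moved, 3 passed the threshold anew and 93 lost it. Of the losses, 27 came with an estimated correlation, 27 with that and genes assigned within 2 kb, and 26 with that and the same-sum scaling. Of 6142 recomputed values of named genes 4911 stayed, 269 moved without a test, 144 passed the threshold anew, 788 lost it and 30 changed sign. Unless an alternative's construction shows it, through fewer peaks tested or fewer libraries, the cause was not tested. Chosen after seeing the data were edgeR, DESeq2, tags without the scaling to 10 M, the estimated correlation, alone or with 2 kb or the same-sum scaling, and leaving out chromosomes 6 and 8 or the stretches at 0. Depth is low in the time course libraries of experiment 5, with 2.01 to 6.2 M tags, and in the CaPS library of experiment 2 in ESC, with 2.63 M tags for CBX7 and 2.23 M for RING1B.

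For CBX7 in ESC (2805 calls, median -0.85), the same-sum scaling gave 184 calls and a median of 0.11, tags without the scaling to 10 M gave 0 calls, the fit without the block gave 2, and leaving out 1 pair gave 1177 to 2761. For RING1B in ESC (9 calls, median -0.67), the same-sum scaling turned the median to 0.074. The calls numbered 126 in the upper part of mean signal, 31 within 1 kb of a transcription start, 0 without the block, 5 with edgeR, 873 with DESeq2, 0 for tags without the scaling, 0 without chromosomes 6 and 8 and 0 to 1099 without 1 pair. H3K27me3 in ESC went from 0 calls to 49 under the same-sum scaling and 15 for tags without the scaling. RING1B in day-8 NPC went from 0 calls to 435 under the same-sum scaling, 37 without the block and 4 for tags without the scaling, where the median was 0.66.

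In the time course of WT, day 6 (2452 calls, median -0.47) had 1152 calls within 1 kb, 1326 without the block, 1 for tags without the scaling and 644 to 2854 without 1 library. Its median was -0.29 with a pseudocount of 5, 0.25 under the same-sum scaling, -0.699 in the upper part and -0.59 to -0.34 without 1 library. Day 8 (3408 calls, median -0.61) had 2208 calls under the same-sum scaling, 1766 within 1 kb, 2 for tags without the scaling and 2118 to 2430 without 1 library. Its median was -0.39 with a pseudocount of 5, 0.36 under the same-sum scaling, -1.07 in the upper part, -0.81 within 1 kb, -0.701 with edgeR, -0.71 with DESeq2, -0.43 for tags without the scaling and -0.71 to -0.54 without 1 library. In CaPS, day 6 (1132 calls) had 1753 with a pseudocount of 5, 314 within 1 kb, 360 without the block, 12 for tags without the scaling, with a median of -0.67 there, and 204 to 1069 without 1 library. Day 8 (2380 calls, median -0.48) had 1576 under the same-sum scaling, 1122 within 1 kb, 1322 without the block, 5 for tags without the scaling and 935 to 1457 without 1 library, and medians of 0.13 under the same-sum scaling, -0.76 in the upper part and -0.066 for tags without the scaling. The difference between genotypes at day 8 (41 calls, median 0.2) had 116 under the same-sum scaling, 13 in the upper part, 0 within 1 kb, 1 without the block, 0 for tags without the scaling and 1 to 91 without 1 library. Its median was -0.18 under the same-sum scaling, 0.43 for tags without the scaling and 0.035 to 0.34 without 1 library. That at day 6 (56 calls) had 15 in the upper part, 0 within 1 kb, 2 without the block, 5 with edgeR, 19 with DESeq2, 0 for tags without the scaling and 0 to 604 without 1 library.

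Among single-column comparisons, RING1B CUT&RUN of CaPS against WT (2324 peaks past 2-fold, median -0.62) had 5492 past 1.5-fold, 945 with a pseudocount of 5, 817 under the same-sum scaling, 1011 in the upper part and 7593 for tags without the scaling. Its medians were -0.48 with the pseudocount, -0.045 under the same-sum scaling, -0.65 in the upper part, -0.65 within 1 kb and -1.34 for tags without the scaling. In the same order, mCaPS against WT (4572, median -0.93) had 7563, 2595, 922, 2715 and 8831 peaks and medians of -0.704, 0.12, -1.04, -0.95 and -1.66. For mCaPS against CaPS (1327, median -0.33), 3930 peaks passed 1.5-fold, 293 the 2-fold threshold with the pseudocount, 344 in the upper part and 836 within 1 kb, with medians of -0.24 with the pseudocount, 0.16 under the same-sum scaling and -0.4 in the upper part. H3K27me3 CUT&RUN (250, median 0.24) had 1053 past 1.5-fold, 159 with the pseudocount, 37 in the upper part and 42 within 1 kb, with medians of 0.22 with the pseudocount, -0.083 under the same-sum scaling, 0.25 in the upper part and 0.19 within 1 kb. In day-10 EB (1332, median 0.15) there were 2683 past 1.5-fold, 426 with the pseudocount, 124 in the upper part and 682 within 1 kb, with medians of 0.13 with the pseudocount, 0.097 under the same-sum scaling and 0.078 in the upper part. H3K27me3 in day-8 NPC (4840, median -1.06) had 2742 under the same-sum scaling, 1807 in the upper part and 1083 within 1 kb, with medians of -0.96 with the pseudocount, -0.094 under the same-sum scaling, -0.88 in the upper part, -0.88 within 1 kb and 1.75 for tags without the scaling.

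Shares of overlapping peaks were lower when at least 50% of the shorter peak had to overlap and higher in the upper part of mean signal, given here in this order. ESC CUT&RUN peaks on RING1B ChIP peaks had 46.9% and 78.5%, the reverse 79.6% and 97.6%. RING1B on H3K27me3 of ESC had 35.1% and 66.8% by ChIP and 51% and 79.1% by CUT&RUN, and H3K27me3 CUT&RUN on H3K27me3 ChIP had 58.5% and 89.4%. ESC RING1B on day-8 NPC peaks had 42.7% and 70.9%, the reverse 59.6% and 87.8%, and day-8 RING1B on H3K27me3 had 58.2% and 86.5%. Day-10 EB on ESC CUT&RUN peaks had 66% and 90.3%, and the reverse 40.7% and 66%.

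Sign changes of named genes came almost all from the same-sum scaling. Log2 ratios of CBX7 that were below 0 became 0.37 at Tbx3, 0.022 at Hoxd11, 0.088 at Pax7, 0.12 at Pax2, 0.21 at Foxa1, 0.19 at Meis2, 0.16 at Nr2f1, 0.11 at Bmi1, 0.14 at Wnt1, 0.26 at Cdkn2a, 0.35 at Cdkn2c, 0.27 at Kit and 0.23 at Neurog2. The change to day 6 in WT became 0.71 at Tbx3, 0.64 at Sox2, 0.42 at Hoxd11, 0.78 at Otx1, 0.58 at Bmi1 and 0.54 at Cdkn2a. That to day 8 in WT became 0.78 at Tbx3, 0.58 at Hoxd11, 0.89 at Otx1, 0.55 at Foxa1, 0.66 at Bmi1, 0.73 at Cdkn2a and 0.019 at Pdgfra, and that to day 8 in CaPS 0.604 at Cdkn2a and 0.48 at Neurog2. Without the WT day-8 library of experiment 3, Cbx2 turned from 0.25 to -2.75 for the change in WT and from -0.46 to 2.54 for the difference between genotypes, and without that of experiment 5 the values were 3.25 and -3.46.

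The fit without the block turned no sign, lost the calls of 94 of 438 values of named genes and of 4 of 120 lists, and changed no other call beyond the counts given here. Where leaving out 1 pair of a comparison of 2 pairs left no residual degrees of freedom, it gives a value with no test. In the time course the lone library left in a group is assumed to vary like the other groups. A stricter threshold on the authors' peak scores could not be run because every score is 0, and comparisons with the knockout were not run because no column of the tables used here holds it.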

Other observations

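RING1B at the list of germ cell genes did not differ from other genes by camera in CaPS cells from ESC to day 8 (n = 2; adjusted p = 0.177), although 5 of the 7 measured genes fell and Prdm1, a regulator of their specification, rose by 1.67. The list's median relative to all genes was -1.38 on the log2 scale, at percentile 0.17 of matched lists. Its members Ddx4, the germ cell helicase (13:112651484-112653349, promoter), and Tdrd1 changed by -3.86 (SE 0.64, limma adjusted p = 1.74e-07) and -2.41. Outside the list the 10 largest falls included some at genes with germ cell functions, a grouping made after the results were seen and not tested for enrichment. At the promoter of Piwil2, of the piRNA pathway (14:70428413-70429966), 1 of the 2 day-8 libraries stood at about 0, so the log2 value depends on the 1 added to it. RING1B fell there from 59.9 ± 14.7 to 3.26 ± 4.6 tags per 10 M (log2 -4.45, SE 0.54, limma adjusted p = 1.16e-13). At Spata22, a meiotic recombination gene, it fell from 87 ± 8.43 to 4.43 ± 0.714 (log2 -4.02, adjusted p = 9.58e-14), and the log2 change was -4.34 at Sycp2, of the synaptonemal complex (2:178406838-178407628, intron 1), and -3.9 at Rhox13. In WT the changes were -2.74 at Piwil2 (adjusted p = 6.62e-06), -2.49 at Spata22, -1.96 at Sycp2 and -2.35 at Ddx4, and the difference between genotypes did not pass at any of these (adjusted p = 0.53, 0.534, 0.509 and 0.692).

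The loci of Gata4 and Gata6, regulators of endoderm, had less RING1B in CaPS day-8 NPC than in CaPS ESC, and less H3K27me3 than in WT day-8 NPC. RING1B at the peak in Gata6 annotated to 1010001N08Rik was 288 ± 115 tags per 10 M in CaPS at day 8 against 2064 ± 112 in CaPS ESC, while in WT the log2 change was -0.47 (adjusted p = 0.495) and the difference between genotypes passed (-2.43, adjusted p = 0.0417), though it was lost without any 1 of the experiment 5 libraries (0.417 to 1). H3K27me3, with 1 column per genotype and no test, was 141.2 against 1828 there and 251.6 against 2368 at Gata4, in CaPS and WT at day 8. RING1B at Gata4 was 218 ± 55.6 against 993 ± 427 in the same comparison, without passing the test. RING1B there was lower at day 8 in WT too, without passing (log2 -1.12, limma adjusted p = 0.058). That fall came mostly from experiment 3, with 3011.72 to 747.45 tags per 10 M, against 3000.94 to 2564.45 in experiment 5. The difference between genotypes did not pass (-1.73, adjusted p = 0.397). In the lists used here Gata4 is a mesoderm gene, and H3K27me3 of the mesoderm list lay 0.43 lower than all genes (percentile 0, 25 of 30 below). The endoderm list, which names Gata6, lay 0.17 higher (percentile 95.61, 5 genes below and 8 above). The 2 loci thus do not stand for the endoderm list. A different behaviour was seen at the peak in exon 5 of Cbx2 (11:119027600-119028752), which ranged from 12.23 to 846.51 tags per 10 M over the RING1B libraries of the time course. It had 35.38 and 846.51 in the CaPS libraries of day 6 and 413.09 and 48.37 in the WT libraries of day 8, from experiments 3 and 5, and for CBX7 in WT ESC it had 371.56, 373.97 and 25.17 in experiments 1, 2 and 3.

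The tests by the same-sum scaling for CBX7 and by other splits of the samples, and the criterion applied to the stretches at 0, were chosen only after the results were seen. For the lower CBX7 and RING1B of CaPS ESC, only 103 of the 2801 peaks called lower for CBX7 stayed called lower under the same-sum scaling. The median log2 value of the 2805 calls, in the direction of the call, went from 1.17 (quartiles 0.99 and 1.4) to 0.15 (-0.03 and 0.39), so a factor per library such as immunoprecipitation yield could account for most of that fall, and an effect of the CaPS form that is even over all peaks stays open beside it. The stronger falls at neural progenitor genes are likewise in line with peak strength, since their median lay at percentile 61.17 of lists matched on signal. The 6 libraries allow 10 splits, too few for a share under 0.05; for CBX7 1 split had as many calls as the real one, itself with 2805, and the highest other had 761. For RING1B the real split had 9 calls and 3 splits, itself included, had as many, with 1747 as the highest other. The splits with 761 and 1747 part only the pair of experiment 2, so under the block they test the difference of CaPS and WT in that pair and are no grouping free of it. The other splits parting 3 pairs called 0.

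For the regional differences, the RING1B falls on chromosome 8 were set against a copy number difference between the cells: CBX7 on chromosome 8 lay at -0.17 relative to the other autosomes, between the bounds set for and against it, so a difference in copy number stays open. The other antibodies argue against a difference confined to RING1B in ESC. There CBX7 (-0.2 to -0.09) and H3K27me3 (-0.47 to -0.32) lay below 0 in each pair. A change shared by CBX7, RING1B and H3K27me3 was not told apart from copy number. RING1B had -0.23 and H3K27me3 -0.43 there in ESC, and RING1B in day-8 NPC had -0.13, below 0 in both pairs (-0.17 and -0.1). Chromosome 6, below the others in ESC as well, had 0.05 for RING1B in day-8 NPC. The stretches at 0 in CUT&RUN were set against deletions carried by the CaPS or WT cells. The lowest ratio of RING1B ChIP over them was 0.478 (interval 0.399 to 0.574, chromosome 5, experiment 2), where a deletion in all cells would leave no tags. This lay below the bound of 0.5 set beforehand, and the deletion is set aside only because every interval lay above 0.1, so a deletion in the cells of the CUT&RUN experiment alone could still exist. Other sources of the values at 0, a step of the processing among them, were not tested. Without the 40 peaks of the stretches RING1B CUT&RUN had 2240 peaks lower and 44 higher in CaPS than in WT past 2-fold.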
